A study of Mus musculus with 2 samples.

How the data were processed

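H3K36me3 ChIP-seq peaks from the heart of mouse embryos of 11.5 days were taken as deposited. There were 2 biological replicates, each joining 3 technical replicates, and both belonged to 1 group, per the labels. Each label's replicate number was used, and no sample was left out. The 4 narrowPeak lists on the genome build mm10 were 1 per replicate, 1 called on the reads of both replicates, and 1 of replicated peaks. Each replicate's list was made from that replicate's alignments and the same 2 further files, and the replicated list from the other 3 lists, per the file list deposited with each sample. The aligner, the peak caller, its threshold and the rule of the replicated list are not given in the sources used here. Read numbers were not used here, so the depth of each replicate is unknown, and a peak absent from a list may have been missed for lack of reads.

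The deposited peak score is a whole number of the narrowPeak format and was not used for any result. The deposited fold of a peak is the ratio over control as the authors gave it, and was used only to describe and rank peaks within a list. The deposited −log10 p and −log10 q per peak are the authors' values as well. The lowest −log10 p was 2.01 in replicate 1, 2.00 in replicate 2 and 2.05 in both other lists, while the lowest −log10 q was 0.402 in replicate 1, so the lists also hold weak peaks. A −log10 q of at least 2 held for 96866 peaks of replicate 1 and 107890 of replicate 2. Only 2 peaks had the same coordinates in both replicates, so the lists were counted as separate samples.

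Genes, exons, coding sequence and untranslated regions were taken from GENCODE release M21, whose build GRCm38 is mm10, after the chromosome lengths were checked against the reference sequence. Peaks on scaffolds were left out of gene results. The covered share of a gene is the percent of its body, from annotated start to end, under peaks of 1 replicate, without regard to strand, so a peak in 2 overlapping genes counts for both. Of 21938 protein-coding genes, 4754 overlap another. A covered share depends on the threshold of the peak caller and on depth, and is not a level of the mark. A gene was marked when the share was at least 20% in each replicate. Peaks were called shared when at least 50% of a peak's length lay inside peaks of the other list, and missing from the pooled list when they shared no base with it. Base classes were assigned in the order coding sequence, untranslated region, intron, gene of another biotype and intergenic. In these classes, exon bases of protein-coding genes outside coding sequence and annotated untranslated regions, as in noncoding transcripts, counted as intron. Circular shifts (100) moved all peaks of a chromosome by 1 random distance.

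Profiles used marked genes of at least 10 kb in 20 equal bins. Differences within genes were tested by 2-sided sign-flip permutation across genes (100000 flips). The mean covered share of each of 20 gene lists and 5 gene classes was set against 10000 random lists of protein-coding genes matched on gene length in 20 quantile bins, with a 2-sided permutation p and Benjamini-Hochberg adjustment over the 20 lists or the 5 classes. These permutations run over genes and measure how a list lies among genes, not the spread between animals. Of 311 listed symbols 310 were matched, Ahsp was not, and 3 listed genes are not protein-coding. The samples, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the 2 highest and 2 lowest members of each list, the 10 genes of at least 10 kb with the highest covered share, the 10 with the largest difference between replicates, and the 10 genes with the replicated peaks of highest fold, and any list member may be given with its value. Ties at 0 are summarised.

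Alternatives were other overlap rules, a −log10 q of at least 2, the replicated or pooled list, minimums of 10% and 40%, longer genes (at least 30 kb), the part past the midpoint, genes of every biotype, unmatched lists and each replicate alone. Lists matched on length and GC content (5 GC bins within each length bin), and lists without genes that overlap another protein-coding gene, were added after the data were seen.

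The procedures were tested on simulated data on the real gene coordinates. With 200 genes given peaks over 40% of their bodies, 100% of these were marked, and 0.203% of genes that overlapped none of them. The planted 40% lies above the minimum for a marked gene, so the 100% followed from the construction and checks only the counting. The 0.203% belongs to the simulated peaks and is not a rate of false calls in the deposited lists. Of 50 lists of 8 planted genes, 100% passed 0.05, and of 400 random lists of 15 genes, 5.5% did. Of 200 null sign-flip tests 6% passed 0.05. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.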

Results

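Histone H3 trimethylated at lysine 36 (H3K36me3), a chromatin mark of the bodies of transcribed genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the heart of mouse embryos of 11.5 days. The embryos were of the strain B6NCrl and of mixed sex. The data form 1 group with 2 biological replicates, so no condition was compared with another, and the questions the design allows are how well the replicates match and where in the genome the mark lay. Replicate 1 had 151478 peaks covering 52.6 Mb, and replicate 2 had 153331 peaks covering 58.1 Mb. The mean was 55.3 Mb ± 3.95 (SD, n = 2), or 2.03% ± 0.145 of the chromosomes. The median peak width was 267 bp in replicate 1 and 286 bp in replicate 2. A peak list gives no read number, so the sequencing depth is unknown and no interval that needs it was computed. Every ± below is the SD of the 2 replicates (n = 2), and tests across genes treat genes, which are not independent replicates, as the unit.

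The replicates shared the strong peaks more often than the weak ones. Of the 10000 peaks of highest fold, 83.2% in replicate 1 and 78.2% in replicate 2 had at least 50% of their length inside peaks of the other replicate. Of the 10000 peaks of lowest fold, 32.2% and 25.2% did. Over all peaks the share was 46.6% for replicate 1 and 41.7% for replicate 2. With any overlap of 1 bp counted, these shares were 59.3% and 56.7%. The Jaccard index of covered bases was 0.321, against a highest value of 0.0149 in 100 circular shifts of the peaks along each chromosome. The fold per peak, which is the authors' value, had a Spearman rho of 0.242 across the 76489 peaks of the replicated list that overlapped both replicates. Covered shares of whole genes had a Pearson's r of 0.951 and a Spearman's rho of 0.924 across 21938 protein-coding genes, 9253 of which had no covered base in either replicate. Both lists were made with the same 2 further files, and the part these have in the agreement between replicates was not tested.

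The authors also deposited 117229 peaks called on the reads of both replicates together, and a replicated list of 90360 peaks. Each replicated peak had the coordinates of a pooled peak, and the list held 77.1% of the pooled peaks. Of the replicated peaks, 82.4% shared at least 50% of either peak's length with a peak in both replicates, and 0% of the 26869 pooled peaks left out did so. The median fold was 3.41 for the pooled peaks kept and 2.83 for those left out.

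Peaks lay almost wholly inside protein-coding genes. Their bodies held 93.8% ± 0.581 of the covered bases, while they make up 38.2% of the chromosomes. In 100 circular shifts the middle 95% of values ran from 39.3% to 43.2%, and the 2-sided permutation p was 0.0198, the smallest that 100 shifts can give. Coding sequence was the most enriched class, with 12.8% ± 0.0256 of the covered bases against 1.33% of the genome, a ratio of 9.63 ± 0.0193. Untranslated regions held 7.19% ± 0.0110 against 1.48%. Introns of protein-coding genes held most covered bases, 73.8% ± 0.566 against 35.4% of the genome. Intergenic sequence held 5.25% ± 0.487 against 55.2%. Long noncoding RNA genes were seldom covered on their own. Of the 6028 that overlapped no protein-coding gene, 22 had at least 20% of their length covered in both replicates, against 303 of the 4127 that overlapped one.

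A gene was called marked when peaks covered at least 20% of its body in each replicate. This held for 3154 of 21938 protein-coding genes (14.4%), while 9253 (42.2%) had no covered base in either replicate. Of the 10 genes of at least 10 kb with the highest covered share, 4 were zinc finger genes of the Zfp series. Zfp110 (chromosome 7, 12834761 to 12850577, mm10) reached 80.8% ± 2.67 and Zfp606 reached 79.98% ± 0.532. Hjurp, which loads the centromeric histone Cenpa, reached 76.6% ± 2.71, and Prrc2a 74.9% ± 1.44. Polrmt, the mitochondrial RNA polymerase, reached 73.5% ± 1.05, and Fasn, the fatty acid synthase, 73.0% ± 1.91. The splicing factors Sf1 and Prpf8 reached 72.6% ± 1.82 and 71.7% ± 3.15. Zfp68 and Zfp90 completed the top 10 with 72.3% ± 3.604 and 71.2% ± 1.90. The call depended on gene length. It held for 3.01% of genes in the shortest decile (median 1.41 kb), 24.6% in the fifth (median 14.5 kb) and 1.32% in the longest (median 186 kb), so the lists below were set against genes of like length. The number of marked genes followed the minimum set for the call, with 5683 at 10% and 674 at 40% of the gene body.

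**Figure D1:**
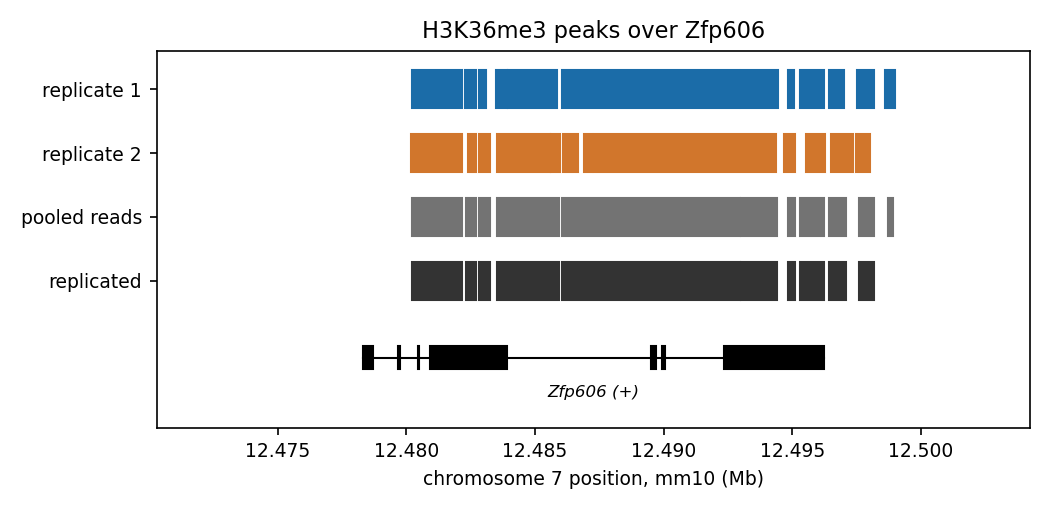
Peaks of the 4 deposited lists over Zfp606 on chromosome 7 (horizontal axis, position in Mb, mm10). Each row of blocks is 1 list, and black boxes on the line below are the gene's annotated exons, merged over transcripts, read from left to right. The blocks leave the start of the gene free and cover 79.98% of its body on average over both replicates.

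Along the 2322 marked genes of at least 10 kb, peaks were nearly absent at the start and covered more towards the end. Peaks covered 1.496% ± 0.232 of the first of 20 equal bins, 39.9% ± 3.53 of bin 10, 48.3% ± 3.67 of bin 17 and 38.8% ± 2.83 of bin 20. The part of the gene past its midpoint was covered to 45.04% ± 3.26 and the part before it to 25.1% ± 1.91. The difference was 20.0 percentage points ± 1.35, with the later part higher in 2036 of 2322 genes (87.7%). A 2-sided sign-flip permutation across genes gave p = 1e-05, the smallest that 100000 flips can give. In the 2 kb around the annotated start, 0.766% ± 0.101 of the bases were covered, against 41.8% ± 2.81 in the 2 kb before the annotated end.

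**Figure D2:**
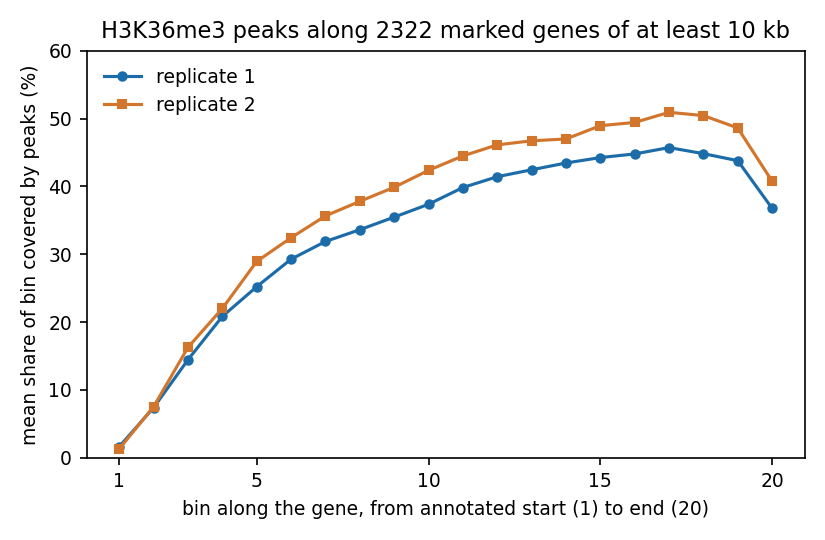
Mean share of each bin covered by peaks (vertical axis, percent) in 20 equal bins from annotated start to annotated end (horizontal axis) of 2322 marked genes of at least 10 kb. Circles are replicate 1 and squares replicate 2. Both lines start below 2% and peak in bin 17, at 45.7% in replicate 1 and 50.9% in replicate 2.

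Exons were covered more than introns of the same genes. In 3050 marked genes with at least 3 exons, peaks covered 47.7% ± 3.19 of the internal exon bases and 32.7% ± 2.35 of the intron bases. The difference was 15.001 percentage points ± 0.837, with exons higher in 2445 genes (80.2%) and p = 1e-05 by the same sign-flip permutation. In the part of the gene past its midpoint alone the difference was 11.7 percentage points ± 0.306 in 2853 genes.

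Genes that dividing cells and energy metabolism need were the most covered of the 20 gene lists. The cell cycle list had a mean covered share of 41.3% ± 0.442, with 14 of 16 genes marked, against 10.8% in random lists of like length. Mcm2 and Mcm3, parts of the replicative helicase, reached 61.4% ± 3.02 and 57.5% ± 0.338, while Ccnb1 and Rrm2 were lowest at 21.7% ± 3.68 and 20.0% ± 1.46. The mitochondrial energy list had 36.8% ± 3.42 and 13 of 16 genes marked, against 10.5%. The ATP synthase genes Atp5b and Atp5a1 led it with 66.0% ± 10.4 and 57.8% ± 5.06, and Cox5a and Pdha1 were lowest with 12.0% ± 3.28 and 11.2% ± 0.0960. The housekeeping list had 27.5% ± 2.26 and 9 of 16 marked, against 9.80%. There Eef2, a translation elongation factor, reached 68.8% ± 5.47 and Hsp90ab1 53.1% ± 12.7, while Eef1a1 had 6.75% ± 1.36 and Hprt 6.42% ± 0.137. Each of these 3 lists had an adjusted p of 0.0005 (2-sided permutation against 10000 random lists, Benjamini-Hochberg over the 20 lists), from the smallest p of 0.0002 that the permutations can give.

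**Figure D3:**
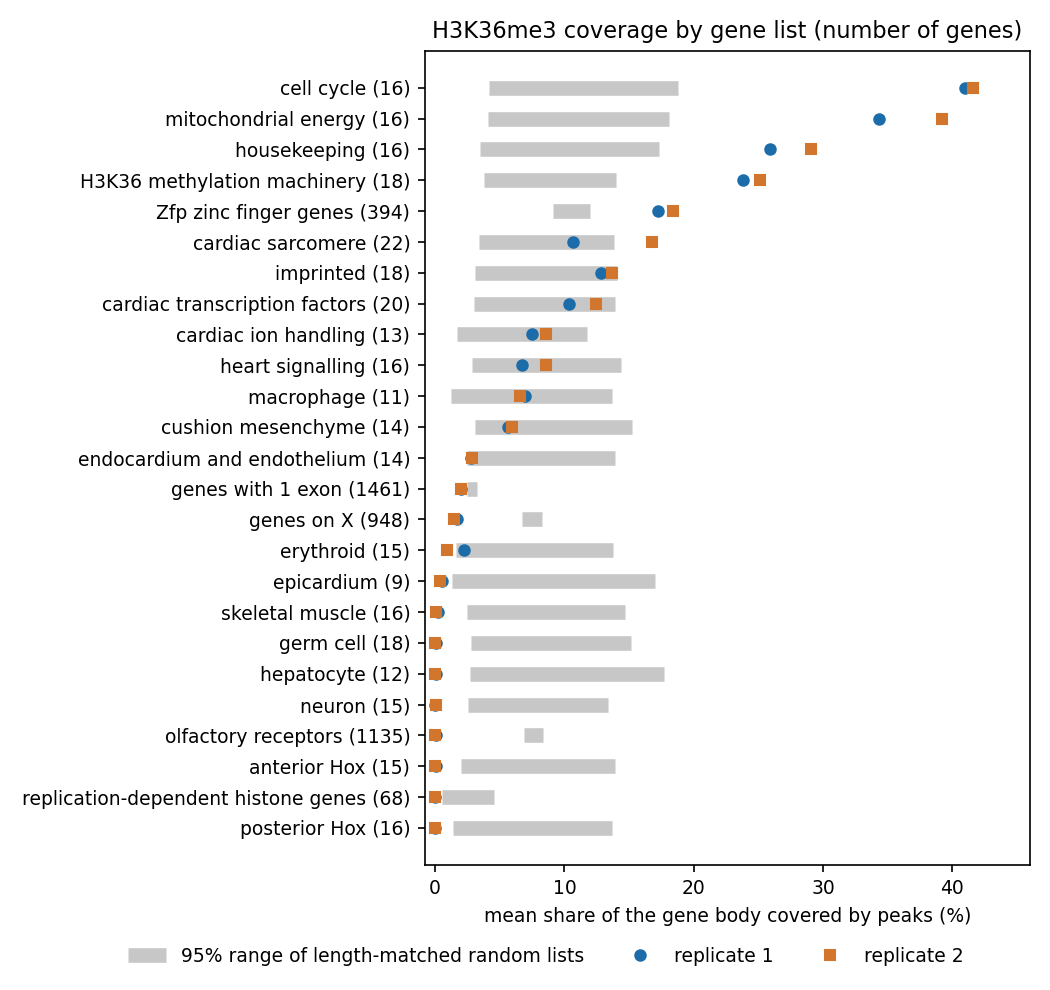
Mean share of the gene body covered by peaks (horizontal axis, percent) for the 20 fixed gene lists and 5 gene classes, with the number of genes in brackets. Circles are replicate 1, squares replicate 2, and grey bars span the middle 95% of 10000 random lists matched on gene length. Cell cycle (41.0% and 41.6%) and mitochondrial energy genes (34.4% and 39.2%) lie right of their grey bars, and posterior Hox genes lie at 0%.

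The lists of heart muscle genes, cardiac transcription factors and heart signalling genes did not pass the test. The cardiac sarcomere list, the contractile apparatus, had 13.7% ± 4.33 against 8.21% in random lists, with 2 of 22 genes marked and an adjusted permutation p of 0.0858. Tpm1 (tropomyosin) had 40.5% ± 1.40 and Mybpc3 (cardiac myosin binding protein C) 38.9% ± 11.5, the marked members. Ttn (titin) had 26.1% ± 13.02, and Myh6 (alpha myosin heavy chain) 20.3% ± 7.76. Myl7 and Tcap had no covered base. The list had 10.7% in replicate 1 and 16.8% in replicate 2, and with replicate 2 alone the list passed, with an adjusted permutation p of 0.0196. In the list of cardiac transcription factors, 4 of 20 genes were marked, with a mean of 11.4% ± 1.46 against 7.98% and an adjusted permutation p of 0.296. These were Srf (37.4% ± 3.71), Gata5 (31.7% ± 4.10), Gata6 (29.9% ± 2.09) and Tbx20 (26.0% ± 6.44), while Hand1 and Isl1 had no covered base. Ion handling genes had 8.03% ± 0.732 against 6.05%, with an adjusted permutation p of 0.491. Atp2a2, the calcium pump of the sarcoplasmic reticulum, was its marked gene with 52.2% ± 1.93, and Casq2 was lowest with 0.585% ± 0.225. Heart signalling genes had 7.61% ± 1.32 against 8.02%, with an adjusted permutation p of 0.947, and the marked genes were Erbb2 (38.1% ± 0.877) and Jag1 (24.2% ± 4.08).

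Of the lists for the other cell types of the heart, the epicardium list alone passed the test. It lay below random lists, with 0.464% ± 0.0786 against 7.85%, 0 of 9 genes marked and an adjusted permutation p of 0.0269. Its highest members were Tbx18 (2.74% ± 0.0149) and Wt1 (0.887% ± 0.605). Endocardium and endothelium had 2.83% ± 0.0535 against 7.45%, with 0 of 14 genes marked and an adjusted permutation p of 0.102. This list passed with replicated peaks (0.0363) and when matched on length and GC content (0.0470), but in no other setting. Eng and Tie1 led it with 9.45% ± 1.66 and 6.21% ± 2.13. Erythroid genes had 1.56% ± 0.913 against 6.97%, with 0 of 15 marked and an adjusted permutation p of 0.0783. All 7 globin genes of this list had no covered base. With replicate 2 alone the erythroid list passed, with 0.915% and an adjusted permutation p of 0.0289. It also passed with replicated peaks (0.0302), at a −log10 q of at least 2 (0.0124) and unmatched (0.0280), but not in the other settings. Epor, the highest erythroid member, was covered in replicate 1 alone and had 9.64% ± 13.6. Cushion mesenchyme had 5.79% ± 0.236 against 8.32% and an adjusted permutation p of 0.491, and its marked gene was Vcan (24.0% ± 0.710), which encodes the matrix proteoglycan versican. Macrophage genes had 6.74% ± 0.309 against 6.39% and an adjusted permutation p of 0.875. Cd68 alone was marked there, with 55.1% ± 4.70. The median of the macrophage list was 0%, and 6 of its 11 genes had no covered base, so its mean depends heavily on Cd68.

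Skeletal muscle, neuron, germ cell, hepatocyte and Hox gene lists were close to free of peaks. Skeletal muscle genes had 0.131% ± 0.141 against 7.80% in random lists, and none of the 16 was marked. Myod1, Myog and Myh3 had no covered base, and Tnnt3 was highest with 0.801% ± 1.13. Neuron genes had 0.0261% ± 0.0241 against 7.31%, germ cell genes 0.0379% ± 0.0537 against 8.19%, and hepatocyte genes 0.0285% ± 0.0403 against 9.30%. The anterior Hox list had 0.0230% ± 0.0326 against 7.22%, with Hoxa3 as its one covered gene (0.346% ± 0.489), and none of the 16 posterior Hox genes had a covered base. Adjusted permutation p-values were 0.0005 for skeletal muscle, neuron, germ cell and anterior Hox, 0.000889 for hepatocyte and 0.0028 for posterior Hox genes. Without genes that overlap another protein-coding gene, 8 anterior Hox genes were left, with 0% covered and an adjusted permutation p of 0.0950.

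Genes of the H3K36 methylation machinery were themselves covered, with 24.5% ± 0.916 against 8.40%, 11 of 18 marked and an adjusted permutation p of 0.0005. The demethylase gene Kdm4a had 63.9% ± 3.20 and Supt6 52.2% ± 3.25. Setd2, which encodes the main H3K36 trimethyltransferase, had 26.8% ± 1.85, and Kdm4c and Phf19 were lowest with 4.38% ± 0.928 and 0.469% ± 0.663. Imprinted genes had 13.3% ± 0.574 against 7.97%, with 3 of 18 marked and an adjusted permutation p of 0.102. The marked genes were Nnat (53.8% ± 4.25), Igf2r (46.7% ± 8.03) and Peg3 (24.0% ± 2.54), while H19, Ndn and Phlda2 had no covered base. Nnat overlaps another protein-coding gene, and peaks in the shared part cannot be assigned to either. Atp5a1, Pdha1, Erbb2, Eng, Supt6, Hoxa3 and Tsr1 also overlap another protein-coding gene. How much of each gene is shared, and how many of its peaks lie there, was not examined.

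Zinc finger genes of the Zfp series stood out among the gene classes. Their mean covered share was 17.8% ± 0.795 against 10.5% in length-matched random lists, with 134 of 394 marked and an adjusted permutation p of 0.00025 over the 5 classes. The peaks of highest fold lay in them as well. Of the 100 replicated peaks of highest fold, 45 had the summit in a Zfp gene, against 2.18% of all replicated peaks. Of these 45 summits, 33 lay in the last exon of the gene, a count that was not set against all replicated peaks. The peak of highest fold lay on chromosome 7 from 12486046 to 12492962, with a fold of 14.4. Its summit was in the coding sequence of the last exon (exon 7) of Zfp606. Zfp777 (fold 13.8, in an untranslated region of the last exon) and Zfp68 (fold 13.5, coding sequence of exon 3) followed. The top 10 by gene also held Zfp146 (12.3), Zfp27 (12.0), Zfp263 (12.0) and Zfp810 (11.7), each with the summit in coding sequence of the last exon, and outside this class Ccdc106 (12.6, intron), Acadl (12.5, intron) and Spred2 (11.7, coding sequence of the last exon). The fold differed between replicates for Zfp777 (15.9 in replicate 1, 9.14 in replicate 2) and Zfp146 (7.85 in replicate 1, 14.7 in replicate 2). The other genes of the top 10 differed less. Olfactory receptor, histone and 1-exon genes were covered less than genes of like length. Olfactory receptor genes had 0.0256% ± 0.0146 against 7.62%, with 0 of 1135 marked. Matched on both length and GC content, random lists had 2.02%, and the adjusted permutation p stayed at 0.00025. Replication-dependent histone genes had 0.00844% ± 0.00167 against 2.23%, with 0 of 68 marked and an adjusted permutation p of 0.0008. Genes with 1 exon had 1.97% ± 0.00950 against 2.85%, with 31 of 1461 marked. Without genes that overlap another protein-coding gene, histone genes had 0% against 1.01% and 1-exon genes 1.02% against 1.65%. Olfactory receptor and 1-exon genes had an adjusted permutation p of 0.00025.

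Genes on the X chromosome were covered less by peaks than random lists of protein-coding genes of like length. The 948 protein-coding genes on X had a mean covered share of 1.57% ± 0.118, against 7.50% in these lists, with an adjusted permutation p of 0.00025. Autosomal means ran from 6.27% ± 0.605 on chromosome 14 to 10.9% ± 1.04 on chromosome 8. On X, 8 genes (0.844%) were marked, named here after their values were seen: Hcfc1 (33.2% ± 1.48), Flna (31.0% ± 2.78), Kdm5c (30.5% ± 1.54), Ddx3x (26.8% ± 9.52), Uba1 (25.1% ± 0.114), Maged1 (25.1% ± 2.53), Gm21887 (24.5% ± 4.97) and Rbm3 (22.8% ± 2.08). The X members of the lists used by every cell were Pgk1 with 17.0% ± 0.162, Pdha1 with 11.2% ± 0.0960 and Hprt with 6.42% ± 0.137, and none was marked. X makes up 6.28% of the chromosomes and held 1.101% of the peaks in replicate 1 and 0.898% in replicate 2. None of the 183 genes on Y was marked.

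**Figure D4:**
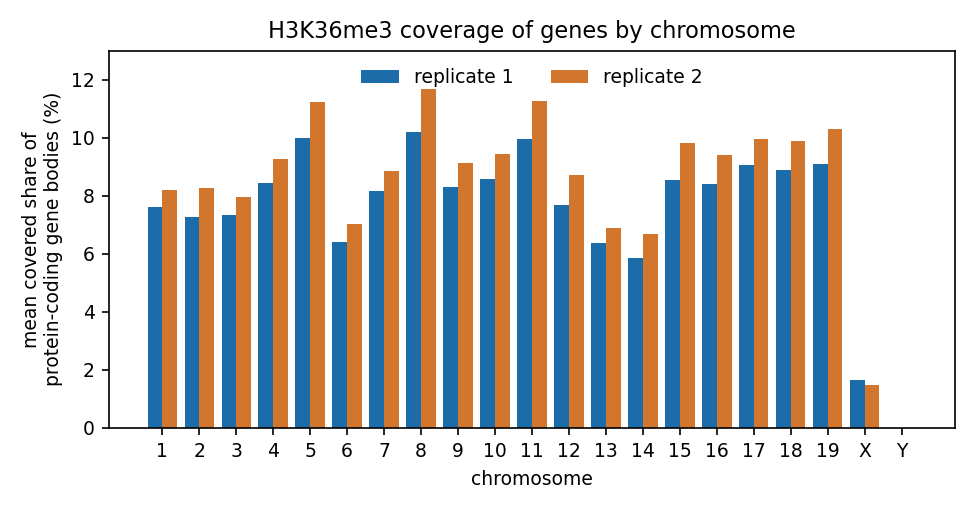
Mean covered share of protein-coding gene bodies (vertical axis, percent) on each chromosome (horizontal axis). Blue bars are replicate 1 and orange bars replicate 2. X has 1.65% and 1.49%, below every autosome, and the bars of Y are too low to see.

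Between the replicates, covered shares were on the whole higher in replicate 2. Among 14164 genes of at least 10 kb, replicate 2 minus replicate 1 had a mean of 1.02 percentage points with an SD across genes of 3.43. Of all 21938 protein-coding genes, 269 reached the 20% minimum in replicate 1 alone and 781 in replicate 2 alone. The 10 genes of at least 10 kb with the largest difference were all higher in replicate 2. Puf60, a splicing factor gene, had 41.6% in replicate 1 and 68.5% in replicate 2, Ykt6 had 19.3% and 45.97%, and Tsr1 had 36.5% and 60.5%. The others were Pofut2, Letmd1, Lamb2, Nxf1, Ube2b, Med25 and Zswim8, down to a difference of 22.0 percentage points. With 1 value per replicate these differences have no test.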

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

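Peaks on unplaced or unlocalized scaffolds stand outside the results on genes and chromosomes. There were 44 such peaks in replicate 1 and 35 in replicate 2, and the pooled and replicated lists held 26 and 19. They were picked out because a signal appears in sequence that no result on genes or chromosomes used. The peak numbers and the share of peaks found in the other replicate did include them. No control peaks were used here to set them against, and no explanation was tested.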

How the results depend on the processing

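Alternatives that match lists on length and GC content, or leave out genes that overlap another protein-coding gene, were chosen after the data were seen. Of 205 values under alternatives, 186 counted as unchanged. For a value with a test this means the same direction and side of the threshold, for the number of marked genes a change of at most 1.5 times, and for other values a move of at most 1 SD of the replicates. All values for the genic share, the position along the gene, the start of genes, exons against introns and the 5 gene classes were among these, although the mean of the random lists set against olfactory receptor genes fell from 7.62% to 2.02% when matched on length and GC content. Settings that changed a value were as follows, and except where the setting's own construction shows it, the cause was not tested. The number of marked genes was 5683 at 10% and 674 at 40% of the gene body. Shared peaks were 58.0% with any overlap of 1 bp and 28.5% with a reciprocal overlap of 50%, against 44.2% ± 3.49 (SD, n = 2), and covered length was 42.5 Mb at a −log10 q of at least 2. The cardiac sarcomere list passed the threshold without genes that overlap another (15.4%, adjusted permutation p 0.0338) and with replicate 2 alone, and single replicates gave 10.7% to 16.8%. Endocardium and endothelium passed with replicated peaks (1.04%, p 0.0363) and when matched on length and GC content (2.83%, p 0.0470). Erythroid genes passed when unmatched (1.56%, p 0.0280), with replicated peaks (0.251%, p 0.0302), at a −log10 q of at least 2 (0.229%, p 0.0124) and with replicate 2 alone, and single replicates gave 0.915% to 2.21%. Anterior Hox genes lost the call without overlapping genes (0%, p 0.0950), where 8 of 15 genes were left. Lists near the random mean crossed it without passing the threshold. These were ion handling when unmatched (8.03%), heart signalling with replicate 2 alone (6.68% to 8.54% over single replicates), and macrophage genes when unmatched (6.74%), when matched on length and GC content (6.74%) and with replicate 2 alone (6.53% to 6.96%). No paired analysis was possible because there is 1 group. The unknown depth limits how far an uncovered gene can be read as lacking the mark.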

Other observations

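The tests of gene length on X, of the joining of peaks, and of length, GC content and share of cells for the gene lists, with the cell cycle list set apart, were chosen after the results they bear on were seen. The tests of GC content, gene families and fold on X, and of peaks missing from the pooled list, were written before their own results, but the GC test was run again after an error had made its first run void, and the pooled pattern was dropped after its results were known and then put back. The design has 1 group, so no biological explanation that rests on a difference between groups was tested.

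In the cardiac sarcomere list, picked after its values were seen, replicate 2 minus replicate 1 was 6.12 percentage points, against a mean of 1.55 in random genes matched on covered share, with 17 of 22 genes higher and 3 lower. With 1 library on each side this difference cannot be tested against the spread between replicates. The comparison with random genes runs over genes only, and it was made for 16 lists. On X, Mid1, a gene at the pseudoautosomal boundary of laboratory mice, was picked after its values were seen. Mid1 held the X peak with the highest −log10 p in all 4 lists, at 34.7 in replicate 1 and 48.0 in replicate 2. Of this gene, 2.92% and 2.83% were covered. Gm21887, 1 of the marked X genes, starts at 170009659, past the end of Mid1 at 170005736. Whether Gm21887 and the Mid1 peaks lie in the pseudoautosomal region was not checked, so they may not reflect the rest of X.

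Few genes on X were marked. The tables argue against gene length as the whole cause, since X genes differed by -5.94 percentage points from length-matched genes, and against GC content, since they differed by -4.61 points from genes matched on both, each with the smallest permutation p of 0.0002. For gene content, families thought to be used by nearly every cell were picked by the first letters of the symbol, such as Eif, Psm and Nduf. Their 27 X members had 6.53% covered and their 516 autosomal members 22.7%, a difference of -16.2 points (permutation p 2e-05), with 2 and 233 marked. Whether each X member is used by most cells was not checked, so this comparison does not decide on gene content. Fewer reads from X in ChIP and control could not be told apart from less of the mark. With fewer reads from X, the fold of X peaks was expected to lie above that of autosomal peaks at the same −log10 p. At a −log10 p from 4 to 6 the median fold of X peaks over that of autosomal peaks was 1.00 in replicate 1 and 1.02 in replicate 2 (mean 1.01). The expected excess was thus absent in replicate 1 and small in replicate 2. Reads per chromosome were not used here, so the part of fewer reads stays open. A lower X dose in a mixed-sex pool, a single active X in females, or both may contribute.

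The list on pooled reads held fewer peaks than either replicate. The tables argue against the joining of neighbouring peaks as the whole cause, since the covered length of the pooled list differed by -3.30 Mb from that of the smaller replicate list. Of the replicate peaks missing from the pooled list, here meaning that they shared no base with it, 93.1% on average also shared no base with the other replicate (93.0% of 50568 and 93.2% of 50336). Of the peaks kept, 14.5% and 18.97% shared no base with the other replicate. The median −log10 p was 3.88 for missing and 5.55 for kept peaks in replicate 1, and 4.15 and 5.99 in replicate 2. Weak peaks of 1 replicate that are lost on pooling would give this order. Pooled reads hold those of both replicates, so a peak found in both is unlikely to be missing, and a high share was likely from the start. The share thus does not tell this apart from a difference in calling, whose threshold is unknown.

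The housekeeping, mitochondrial energy and cell cycle lists (48 genes, 35.2% ± 2.04, n = 2; 32.1% ± 2.84 for 32 genes without the cell cycle list) lay above the lists of single cell types of the heart. The difference of 28.8 percentage points was 25.8 after correction for gene length and 25.4 after correction for length and GC content, each with a permutation p of 1e-05, the smallest that 100000 permutations can give, which argues against either as the whole cause. Without correction for length, heart muscle lists (35 genes, 11.6% ± 2.99) lay 8.08 points above the lists of the other cells (63 genes, 3.53% ± 0.219, permutation p 8e-05). They lay 23.6 points below the first group, or 20.5 without the cell cycle list (permutation p 1e-05 each). The last difference was 17.7 points after correction for gene length (permutation p 1e-05). This is the order expected if a peak list from a whole organ misses marks that few cells carry. Against the share of cells as the whole cause, the cell cycle list, of genes for dividing cells, had 41.3% ± 0.442 and the housekeeping list 27.5% ± 2.26, but the difference of 12.8 points after correction for length (permutation p 0.0301) was 10.2 points without the X genes of the housekeeping list (14 genes left, permutation p 0.0835), a condition added after the first value was seen, so this comparison does not decide. The share of cells may contribute, but the order had been seen before the tests were chosen, cell shares were not measured, and the transcript level of the genes, which was not used here, stays open.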
